A study of Mus musculus with 2 samples.

How the data were processed

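Both libraries were made from total RNA of YFP-positive CD4+ cells, 1 sorted as Thy1.1-negative and 1 as Thy1.1-positive. Cells came from spleen and lymph nodes of Foxp3 ΔCNS1-Cre-R26-YFP mice, were enriched for CD4 with magnetic beads and sorted to a purity typically above 97%. Libraries were built from 3 µg of total RNA with a NEBNext Ultra kit, per the labels' protocols. The authors deposited a table of FPKM values per Ensembl gene, 1 column per population. The P and N in its column names were read as Thy1.1-positive and Thy1.1-negative. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1 and the mouse build mm9. Their settings and the filters are not given in the sources used here. Gene symbols, gene types, transcript lengths and GC content came from the GENCODE M21 annotation, which is on another build than mm9, so positions are not reported. A symbol was found for 40254 of 41592 IDs, 96.8%.

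FPKM is a normalised unit, so no count model was used. Whole reads behind the values were recovered to learn the depth. The deposited values of the 23442 genes above 0 in both libraries stood in ratios of whole numbers times 1 common factor of 1.003, within a tolerance of 2e-12. This fixed the ratio of the library totals. The totals themselves came from genes whose implied length equalled the summed length of their annotated exons, with overlaps counted once. They were 18536339 counted reads for the Thy1.1-negative and 18600581 for the Thy1.1-positive library, and they rest on that length. Each gene's reads were the multiple of its smallest whole numbers that brought the implied gene length nearest to the mean length of its annotated transcripts. For 54.5% of genes with a mean FPKM of at least 1 that length was within 1 base of the annotated mean, and 16.3% needed a multiple above 1. Recovered reads summed to 100.2% and 100.1% of the totals. Their median was 444 and 421 reads per gene with a mean FPKM of at least 1, and 28107 and 25709 genes were above 0 in the Thy1.1-negative and Thy1.1-positive library. Exact Clopper-Pearson intervals at 95% of the share of a gene's reads in each library were turned into intervals of the ratio. They leave out variation between animals, sorts and library preparations, and reads that share a PCR origin.

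With 1 library per population there is no estimate of replicate error, so genes were counted by a rule of size. A gene was called higher or lower when log2(FPKM + 1) differed by at least 1, among genes with a mean FPKM of at least 1. The pseudocount understates the change of genes with low values. For each of 32 gene lists, the median difference over members with a mean FPKM of at least 1 was compared with 10000 random lists of the same size, matched on 20 bins of mean expression. A list with at least 5 such members was said to stand apart when its percentile was under 2.5 or over 97.5. The percentile describes these libraries and is not a test across animals. The lists cover Treg signature genes, genes lower in Treg cells than in conventional CD4 cells, naive and central markers, effector markers, Th1, Th2, Th17 and Tfh genes, and the cell cycle. They also cover interferon response, immediate early, heat shock, interleukin-2 and STAT5, TGF-beta, Foxp3 locus, homing, glycolysis, respiration, ribosomal protein and apoptosis genes. Pan T cell, housekeeping and sex-linked genes served as checks, as did markers of B cells, plasma cells, CD8 T cells, natural killer cells, myeloid cells, dendritic cells, innate-like T cells, erythroid cells and stromal and endothelial cells.

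The genes named in the text followed a rule with 3 parts. Foxp3, Thy1, Il2ra, Ctla4, Ikzf2 and Nrp1 were always named. Named too were the 10 genes with the largest and the 10 with the smallest difference at a mean FPKM of at least 5, leaving out predicted gene models, small RNA genes and antigen receptor gene segments. For each list with at least 5 measured members, the largest and the smallest difference and up to 2 further members with the largest absolute difference were named. Some genes that the rule names are not reported here. The 7SK RNA was treated as a small nuclear RNA, a decision taken after the values were seen. Rpph1, annotated as a ribozyme, was not left out. Among markers of lists with fewer members, Klrb1c, Itgam, Cst3, Lyz2 and Hbb-bs were chosen after their values were seen. The lists, the rules, the naming of genes and the first set of alternatives were fixed before the data were examined.

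Alternatives were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, fold rules of 1.5 and 4, and 4 rescalings. These rescalings brought both libraries to the same sum, centred the median difference of genes with a mean FPKM of at least 5, used the upper quartile of values above 0, or left the 100 highest genes out of the sum. Random lists were also matched on 10 or 50 bins, and lists were also scored by the share of members above the median gene. Restriction to protein-coding genes, at least 50 reads, an interval wholly past 1.5-fold, and matching on length or GC content were added after seeing the data.

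The steps were tested on simulated data drawn from the real libraries' means and totals. Reads were recovered for 97.0% of 12807 genes with a mean FPKM of at least 1. Gene lengths in the simulation were those chosen when the real reads were recovered. A wrongly chosen multiple in the real data would therefore not show in this share. With 49 or 50 genes per size of change, the rule of size found 81.6% of genes changed 2.5-fold, 94.0% of those changed 4-fold, 100% of those changed 8-fold and 2% of those changed 1.5-fold. Intervals held the true ratio for 95.4% of 12391 unchanged genes. They were computed from the simulated reads and not from the recovered ones, so this does not test the effect of recovery errors on them. Of 100 unchanged random lists 6 were said to stand apart, and 50 of 50 lists shifted by 0.3 were found. Simulated genes varied independently and by counting error only. These shares therefore do not give the rate of calls for real lists, whose genes vary together. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.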

Results

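Transcript levels were measured by RNA-seq in a pair of CD4+ T cell populations sorted from the spleens and lymph nodes of C57BL/6 mice aged 6 to 8 weeks. The mice carried Cre under Foxp3 regulatory DNA that lacks CNS1, a conserved noncoding element of the Foxp3 locus, together with a YFP reporter at the Rosa26 locus. Such a reporter marks cells in which Cre has acted, and their progeny. Both sorted populations were YFP-positive, and they differed in Thy1.1 staining. The Thy1.1-negative population and the Thy1.1-positive population were each represented by 1 library, so no difference has a replicate check and none carries a p-value. The series set out to compare thymus-derived regulatory T (Treg) cells with exFoxp3 precursor cells, but its design text gives the same marker pair to both. The populations are therefore named here by the markers in the sample titles. Depth was alike, with 18536339 counted reads in the Thy1.1-negative library and 18600581 in the Thy1.1-positive library. All differences are Thy1.1-negative minus Thy1.1-positive. Intervals are 95% counting intervals of the ratio of FPKM values, which are fragment counts normalised to gene length and library total, and cover counting error only.

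Both libraries held abundant transcripts of the Treg lineage. Foxp3, the transcription factor that defines Treg cells, stood at 158 FPKM in the Thy1.1-negative library and 237 FPKM in the Thy1.1-positive library, a ratio of 0.670 (0.647 to 0.693). Il2ra, which encodes CD25, a chain of the high-affinity interleukin-2 receptor, was lower still in the Thy1.1-negative library, at 98.8 against 205 FPKM, with a ratio of 0.482 (0.466 to 0.499). Ctla4, an inhibitory receptor of Treg cells, was nearly level at 1156 and 1105 FPKM, a ratio of 1.05 (1.03 to 1.07). Nrp1, a surface receptor often found on thymus-derived Treg cells, stood at 53.9 and 54.5 FPKM, and its interval of 0.954 to 1.03 included 1. Ikzf2, which encodes the transcription factor Helios, had a ratio of 0.904 (0.884 to 0.924). Rescaling by the upper quartile turned the sign of the difference for both Ikzf2 and Nrp1. Thy1 was 1.60-fold higher in the Thy1.1-negative library (1.54 to 1.66), at 246 against 153 FPKM. Values for this gene do not separate the Thy1.1 allele from Thy1.2, so they do not check the sort.

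Across the 12820 genes with a mean FPKM of at least 1, 247 were at least 2-fold higher in the Thy1.1-negative library on the log2(FPKM + 1) scale and 148 were at least 2-fold lower. The other 12425 genes, 96.9%, lay within 2-fold. Among the 10657 protein-coding genes, 190 were higher and 58 were lower. At a mean FPKM of at least 5, predicted gene models, small RNA genes and receptor gene segments accounted for 16 of 107 higher and 28 of 60 lower genes. Across all genes with a mean FPKM of at least 1, the log2(FPKM + 1) values of the libraries had a Pearson r of 0.980, where genes are not independent replicates. In simulated libraries, counting error alone put 82 of the 12391 genes left unchanged past the same rule. Rescaling by the upper quartile moved the median difference of all genes up by 0.23, from 0.03 to 0.26, and gave 398 higher and 82 lower genes.

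At a mean FPKM of at least 5, with predicted gene models, small RNA genes and receptor gene segments left out, the genes with the largest differences encode S100 proteins, galectins, an effector protease and parts of the proliferation machinery. The calcium-binding proteins S100a6 and S100a4 were 10.4-fold (8.86 to 12.3) and 9.22-fold (8.01 to 10.7) higher in the Thy1.1-negative library, at 125 against 11.96 FPKM and 241 against 26.2 FPKM. The galectins Lgals3 and Lgals1 were 11.6-fold (7.60 to 18.7) and 4.51-fold (4.17 to 4.89) higher. Gzmb, the cytotoxic protease granzyme B, reached 19.7 FPKM against 3.56. Ccr2, a receptor for inflammatory chemokines, reached 14.1 FPKM against 1.51. Stmn1, a microtubule regulator, was 9.45-fold higher and Mki67, the proliferation marker Ki-67, 9.003-fold higher. Pclaf, a partner of the replication clamp PCNA, was 9.95-fold higher, and Rrm2, a subunit of ribonucleotide reductase, 6.11-fold higher.

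In the other direction, Rpph1, the RNA component of ribonuclease P, was 6.28-fold higher in the Thy1.1-positive library (4.03 to 10.2), with 145 reads against 23. Its annotated type is ribozyme, so the rule did not leave it out with the small RNA genes. Rn7sk, left out as a small nuclear RNA after its values were seen, was also higher in the Thy1.1-positive library. Gsta4, a glutathione transferase, was 4.09-fold higher there, at 25.1 against 6.14 FPKM. Arhgap20, a GTPase-activating protein, was 3.98-fold higher, and Dgat2, which catalyses the last step of triglyceride synthesis, was 3.61-fold higher. Ecm1, a secreted matrix protein, was the most abundant of this set, at 241 FPKM in the Thy1.1-positive library and 97.48 FPKM in the Thy1.1-negative library. The remaining 5 were Lad1 at 3.11-fold, Evx1 at 2.92-fold, Ppm1l at 2.76-fold, Rgs9 at 2.71-fold and Sdc4, the proteoglycan syndecan-4, at 2.67-fold. With a pseudocount of 5, Evx1 and Sdc4 lay within 2-fold.

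**Figure D1:**
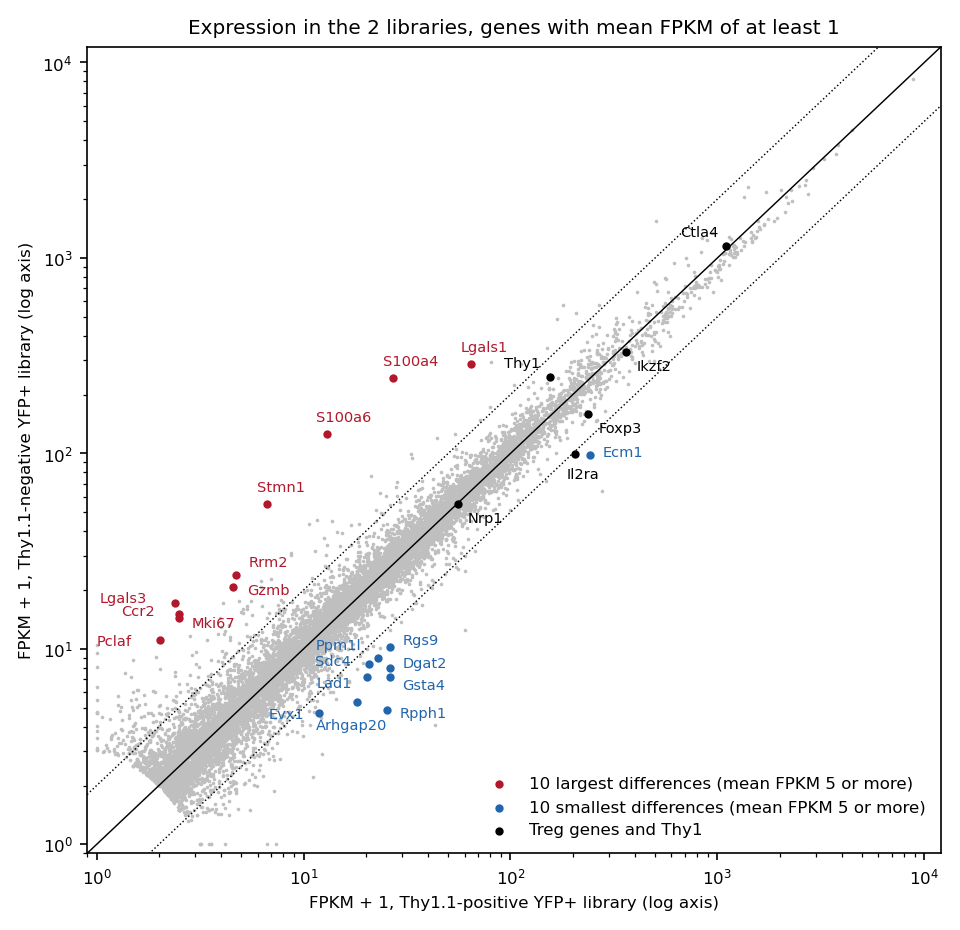
FPKM + 1 of each gene with a mean FPKM of at least 1 in the Thy1.1-positive library (horizontal log axis) and the Thy1.1-negative library (vertical log axis), 1 library each, with equality drawn solid, 2-fold differences dotted, and in red and blue the 10 largest and 10 smallest differences at a mean FPKM of at least 5, without gene models, small RNA genes and receptor segments. Foxp3 at 158 against 237 FPKM and Il2ra at 98.8 against 205 FPKM lie under the line, and S100a4 at 241 against 26.2 FPKM lies far above it. Rpph1, annotated as a ribozyme, was kept among the blue points.

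The Treg signature as a group was lower in the Thy1.1-negative library. Of its 23 measured members, 17 lay below 0 and 6 above, with a median log2 difference of -0.19, at percentile 0.01 of 10000 random lists matched on expression. Past 2-fold were Gpr83, an orphan receptor enriched in Treg cells (ratio 0.445), Swap70 (0.456), Ikzf4, which encodes the transcription factor Eos (0.479), and Il2ra. Klrg1, a marker of terminally differentiated effector cells, went the other way at 2.07-fold higher, but lay within 2-fold when centred on the median gene, without the 100 highest genes or with a pseudocount of 5. None of those 4 lower genes passed 2-fold after rescaling by the upper quartile, where their differences were -0.86, -0.85, -0.80 and -0.79, and Gpr83 and Swap70 did not with a pseudocount of 5 either, at -0.92 and -0.97. Rescaled in that way, 12 of the 23 members lay above 0 and the median was 0.06, while its distance to the median gene was -0.20 against -0.22 with the deposited values. Scored by the share of members above the median gene, 26.1%, the list lay at percentile 3.14 and no longer stood apart.

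Genes that Treg cells normally express less than conventional CD4 cells went both ways, with 6 of 11 measured members above 0 and 5 below. Of these, Cd40lg, the ligand of the costimulatory receptor CD40, was 2.42-fold higher and Pde3b, a phosphodiesterase, 2.84-fold higher, and none was 2-fold lower. With a pseudocount of 5 both lay within 2-fold, at 0.85 and 0.59. Bach2, a repressor of effector differentiation, had a ratio of 0.619, and Dapl1, with 18 against 7 reads, a ratio of 2.58 (1.03 to 7.31). The median was 0.23 at percentile 98.4, but it was -0.05 among members with a mean FPKM of at least 5, and 54.5% of members lay above the median gene, at percentile 62.2. None of the 18 naive and central markers passed 2-fold, and their median was -0.12 at percentile 1.26. Ccr7, the receptor that guides T cells into lymph nodes, stood at 270 FPKM in the Thy1.1-negative library and 520 FPKM in the Thy1.1-positive library, while Igfbp4 had a ratio of 1.62. This median was 0.14 after rescaling by the upper quartile, -0.12 from the median gene, and 38.9% of members lay above the median gene, at percentile 22.6.

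**Figure D2:**
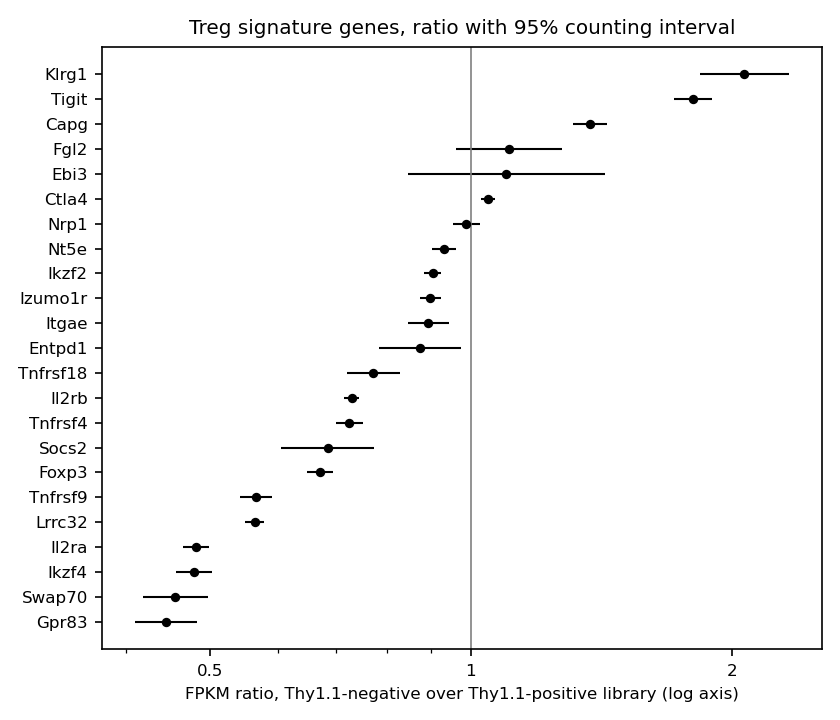
Ratio of FPKM in the Thy1.1-negative library over the Thy1.1-positive library (horizontal log axis) for the 23 Treg signature genes, with points for the ratio and bars for its 95% counting interval, 1 library per population. Ratios run from 0.445 for Gpr83 to 2.07 for Klrg1, with Foxp3 at 0.670; 17 lie below 1 with the deposited values and 11 after rescaling by the upper quartile.

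Effector and activated T cell markers were higher in the Thy1.1-negative library. Of 32 measured, 15 were at least 2-fold higher and none 2-fold lower, with a median of 0.86 at percentile 100. S100a6, S100a4 and Ccr2 led the list, and Gzmb and Lgals1 also belong to it. Tnfrsf9, the costimulatory receptor 4-1BB, had the lowest difference, at 146 against 258 FPKM. Among 24 chemokine receptors and homing genes, 8 were 2-fold higher and none 2-fold lower, with a median of 0.27 at percentile 99.97, or 0.51 after rescaling by the upper quartile. Ccr4 was 3.90-fold higher, Cxcr3 3.46-fold higher and Ccr2 9.37-fold higher, whereas Ccr7 had the lowest difference. Ccr2 is also in the effector list, Cxcr3 also in the Th1 list and Ccr4 also in the Th2 list, so these lists share genes.

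Genes of several helper T cell programmes were higher as well. Of 15 Th1 genes, 3 were 2-fold higher, among them Cxcr3 and Tbx21, which encodes the Th1 regulator T-bet (2.502-fold), and none was 2-fold lower, with a median of 0.35 at percentile 99.98. Hopx, at 37.9 against 49.3 FPKM, had the lowest difference of that list. Cxcr3 also belongs to the effector list, as does 1 more of those 3. Of 13 genes of T follicular helper (Tfh) cells, 7 were 2-fold higher and none 2-fold lower, with a median of 1.004 at percentile 100. Of those 7, 1 also belongs to the effector list. Tox2, a nuclear factor expressed in Tfh cells, was 2.76-fold higher. Sostdc1 had 113 reads against 2, a ratio of 56.7 (15.3 to 474). Pou2af1, a coactivator best known from B cells, was 9.18-fold higher, and Bcl6, the main regulator of Tfh cells, had a ratio of 0.763. With a pseudocount of 5, Tbx21, Sostdc1 and Pou2af1 lay within 2-fold. B cell markers were higher in the same library, with a median of 0.58, and are given with the other cell types.

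Of 7 measured Th17 genes, 2 were 2-fold higher and none 2-fold lower. Tmem176a, 1 of these, was 3.93-fold higher at 2.44 against 0.622 FPKM, but within 2-fold with a pseudocount of 5. Tmem176b had a ratio of 1.86 and Stat3, at 352 against 527 FPKM, a ratio of 0.667. The list had a median of 0.30 at percentile 98.2, and at percentile 97.2 with a pseudocount of 0.1. Of 7 measured Th2 genes, Ccr4 was 2-fold higher and none 2-fold lower. Ccr8 had a ratio of 0.602, Gata3, the main Th2 regulator, a ratio of 0.782, and Il1rl1, the interleukin-33 receptor, a ratio of 1.28. The Th2 list did not stand apart, with a median of -0.14 at percentile 4.57 and a mean of the opposite sign, 0.10; after rescaling by the upper quartile the median was 0.11, -0.15 from the median gene. By the share of members above the median gene, the Th1, Tfh and Th17 lists lay at percentiles 95, 96.8 and 89.9, inside the range of random lists.

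Cell cycle genes had a median of 1.05 at percentile 100, which was 0.62 with a pseudocount of 5 and 1.55 with a pseudocount of 0.1. Of 36 measured, 20 were at least 2-fold higher in the Thy1.1-negative library and none 2-fold lower. Aurkb, a mitotic kinase, was 15.3-fold higher (7.81 to 34.1), from 137 against 9 reads, and Stmn1, Mki67 and Rrm2 belong to this list too. Tk1, a thymidine kinase, was the member with a negative difference, at 24.6 against 28.6 FPKM, and its sign turned after rescaling by the upper quartile. Together with the effector list, these made 35 different genes at least 2-fold higher.

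Metabolic genes differed by smaller amounts, none past 2-fold. Among 16 glycolysis genes, 15 lay above 0, with a median of 0.34 at percentile 99.99, or 0.59 after rescaling by the upper quartile. Tpi1, Pgam1 and Pgk1, enzymes of the pathway, had ratios of 1.66, 1.55 and 1.52, and Slc16a3, a lactate exporter, had a ratio of 0.545. Of 26 mitochondrial respiration genes, 24 lay above 0, with a median of 0.16 at percentile 99.2, or 0.41 by the upper quartile. Uqcrfs1, at a ratio of 1.26, Ndufa9 at 1.24 and Atp5j at 1.21 led it, and Ndufb8 at 0.977 was lowest, with a sign that turned after rescaling by the upper quartile. Matched on gene length as well as expression, that list lay at percentile 97.1. Of 36 cytosolic ribosomal protein genes, 35 were lower in the Thy1.1-negative library as deposited, with a median of -0.19 at percentile 0.02 that became 0.07 after rescaling by the upper quartile, -0.19 from the median gene. Rpl13, Rps19 and Rps14 had ratios of 0.795, 0.797 and 0.810. Rpsa, at 1.01, was the exception, and its sign turned under the other 3 rescalings.

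Genes of interleukin-2 and STAT5 signalling were lower in the Thy1.1-negative library under every rescaling tried, with a median of -0.42 at percentile 0 over 16 genes that was -0.17 by the upper quartile, -0.44 from the median gene. Il2ra was 2-fold lower with the deposited values but not after rescaling by the upper quartile, where it stood at -0.79, and none was 2-fold higher. Cish, a feedback inhibitor induced by STAT5, had a ratio of 0.641, Myc a ratio of 0.625 and Il2rg, the common cytokine receptor chain, a ratio of 1.13. By the share of members above the median gene, 25.0%, the list lay at percentile 4.56. Genes of the TGF-beta pathway were also lower, with 13 of 15 below 0 and a median of -0.27 at percentile 0. Their median was -0.02 after rescaling by the upper quartile, and its distance to the median gene was -0.28 against -0.30 with the deposited values. Pmepa1, a TGF-beta target, had a ratio of 0.511, Smad7, an inhibitor of the pathway, 0.682, Tgfb1 itself 0.708 and Smad3 1.26. None of these 15 passed 2-fold. Immediate early and T cell receptor-induced genes had a median of -0.17 at percentile 0.105, with 17 of 23 below 0 and none past 2-fold. Nr4a2 and Nr4a1, receptors induced by antigen signalling, had ratios of 0.632 and 0.672, Myc belongs here too, and Cd69 had a ratio of 1.24. Their median was 0.09 after rescaling by the upper quartile, -0.18 from the median gene.

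Interferon response genes were higher, with 24 of 25 above 0, 2 at least 2-fold higher, none 2-fold lower and a median of 0.33 at percentile 100, or 0.58 after rescaling by the upper quartile. Oas1a, an antiviral oligoadenylate synthetase, was 2.45-fold higher and Ifi27l2a 2.15-fold higher, at 571 against 266 FPKM. Rsad2, which encodes viperin, had a ratio of 2.07 but lay within 2-fold on the log2(FPKM + 1) scale. Gbp3, at 0.842, was the exception, and its sign turned after rescaling by the upper quartile. The 25 regulators of the Foxp3 locus did not stand apart, with a median of -0.02 at percentile 18.6 and a mean of 0.08, and with a median of 0.22, -0.04 from the median gene, after rescaling by the upper quartile. Uhrf1, which recruits the maintenance DNA methyltransferase, was 3.68-fold higher in the Thy1.1-negative library. Dnmt1, that methyltransferase, had a ratio of 1.56, Ezh2, a histone methyltransferase, 1.53 and Stat5a 0.645. None of the others passed 2-fold.

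The 11 heat shock genes had a median of 0.08 at percentile 76.2 and the 19 apoptosis genes a median of 0.07 at percentile 68.4, neither with a member past 2-fold. Hspa1a, Hspa1b, Hspb1 and Hspe1 had ratios of 1.99, 1.57, 0.643 and 0.853, and the sign of Hspe1 turned after rescaling by the upper quartile. The survival genes Bcl2l1 and Bcl2 had ratios of 0.623 and 0.666, and the death gene Bad a ratio of 1.72. The 24 lists with at least 5 measured members included 18 that stood apart, 12 higher and 6 lower. Among the higher ones were pan T cell genes (0.26, percentile 99.92) and B cell markers (0.58, percentile 99.99), which served as checks. Standing apart therefore does not by itself separate a programme from the checks. After rescaling by the upper quartile every median above 0 was larger, at 1.11 for effector, 0.59 for Th1, 0.54 for Th17, 1.25 for Tfh and 1.28 for cell cycle genes, 0.48 for genes lower in Treg cells, 0.33 for heat shock, 0.29 for apoptosis and 0.27 for sex-linked genes, and no call of these lists ended. About 1.2 would be called by chance if genes were independent, but genes of a list vary together and are not replicates.

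**Figure D3:**
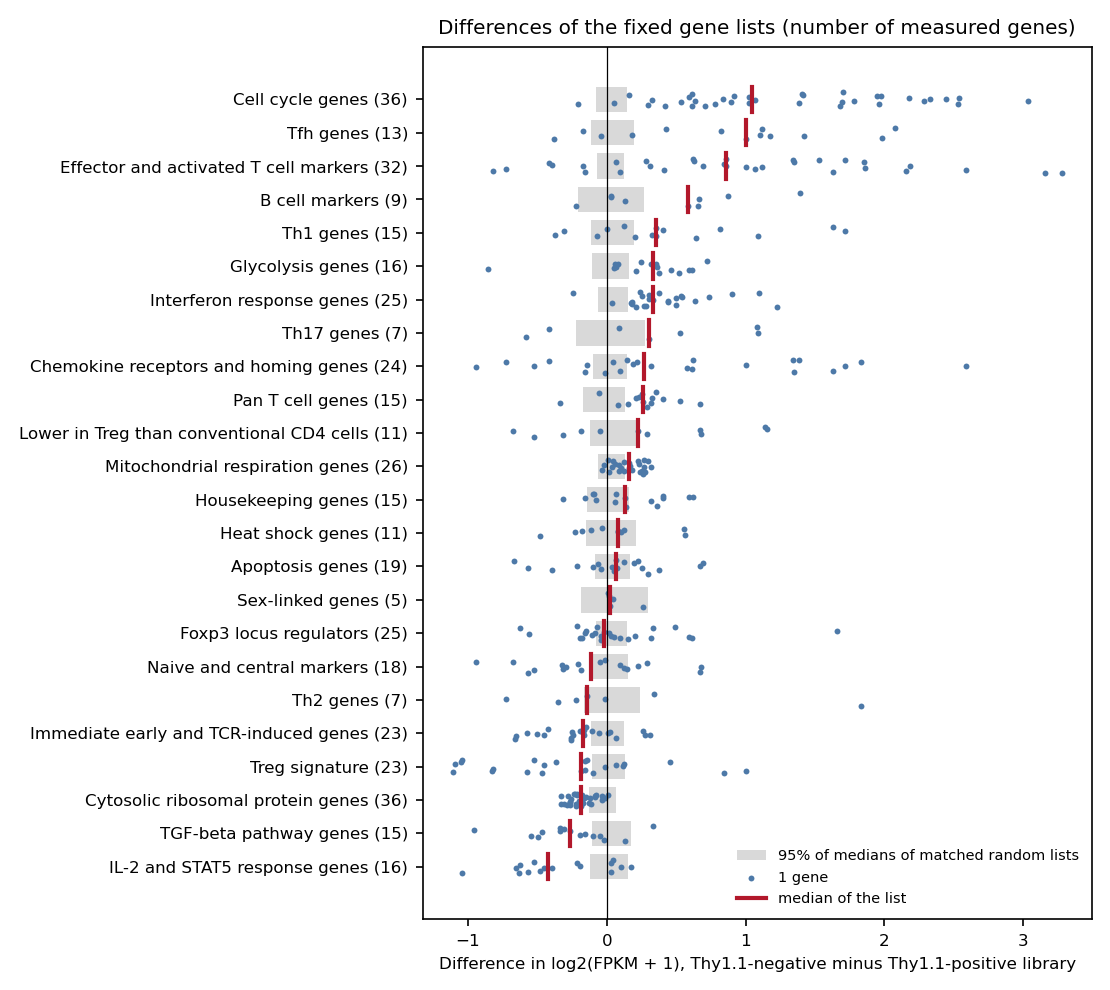
Difference in log2(FPKM + 1), Thy1.1-negative minus Thy1.1-positive library (horizontal axis), for the measured genes of each list (points), with the list's median (red line) and the middle 95% of medians of random lists matched on expression (grey band). Cell cycle genes have a median of 1.05 and interleukin-2 and STAT5 response genes a median of -0.42; the negative medians of the Treg signature, naive, immediate early, ribosomal protein, Th2 and Foxp3 locus lists are positive after rescaling by the upper quartile.

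Pan T cell genes were somewhat higher in the Thy1.1-negative library, with 13 of 15 above 0, none past 2-fold and a median of 0.26 at percentile 99.92, or 0.52 after rescaling by the upper quartile. Cd4 stood at 471 against 327 FPKM and Cd3g had a ratio of 1.32. Housekeeping genes did not stand apart, with a median of 0.14 at percentile 95.8, or 0.39 by the upper quartile, and none past 2-fold, although Actb was 1.54-fold higher. Hprt had a ratio of 1.33. Of the 5 measured sex-linked genes, none passed 2-fold and the median was 0.02 at percentile 46.8. Ddx3y, a Y-linked gene, stood at 60.5 and 60.1 FPKM, Eif2s3y at 43.6 and 42.2 FPKM, and Kdm5d had a ratio of 1.23. The signs of Ddx3y and of Uty, at 1.02, turned under other rescalings.

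B cell markers were higher in the Thy1.1-negative library, with a median of 0.58 at percentile 99.99 over 9 measured genes, 1 of them at least 2-fold higher and none 2-fold lower. Igkc, an antibody light chain constant region, was 2.76-fold higher at 33.1 against 11.98 FPKM, Cd22 stood at 5.59 against 2.60 FPKM and H2-Aa at 1.52 against 0.592 FPKM. Cd79a, a chain of the B cell receptor complex, went the other way at 1.63 against 2.07 FPKM, with an interval of 0.519 to 1.19. With a pseudocount of 5 the median was 0.22, by the upper quartile it was 0.79, and with a pseudocount of 0.1 Cd22 and H2-Aa passed 2-fold too. Without the filter on low values the list's median was 0.05 at percentile 54.3, and by the share of members above the median gene it lay at percentile 85.1. The other cell type lists had fewer than 5 measured members and are given as values. Of 3 natural killer cell markers, Klrb1c was 2-fold higher at 2.08 against 0.445 FPKM. Of 2 measured myeloid markers, Itgam was 2-fold higher at 4.17 against 0.272 FPKM, and Cst3 had a ratio of 1.27 at 63.5 against 50.1 FPKM. Lyz2, an abundant macrophage transcript, was not among the measured genes, at 0.298 and 0.212 FPKM. The measured erythroid marker, Hbb-bs, was 2-fold lower at 0.747 against 2.51 FPKM. The 3 plasma cell, 2 dendritic cell, 2 stromal and endothelial and 1 CD8 T cell markers lay within 2-fold, and none of the 6 innate-like T cell markers in the data reached a mean FPKM of 1.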

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

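Each result came from 1 library per population, so depth limits the precision of a ratio but says nothing of variation between animals, and leaving out a replicate was not possible. No paired analysis was possible because each population has 1 library and the labels give no shared numbers. Of 26 alternative counts, 11 stayed within 1.5 times the count in the report and 15 did not. Higher and lower genes, 247 and 148 in the report, numbered 402 and 293 with a pseudocount of 0.1, 72 and 19 with a pseudocount of 5, 107 and 60 at a mean FPKM of at least 5, 745 and 493 by the 1.5-fold rule and 31 and 9 by the 4-fold rule; fewer or more genes can pass these by construction. They numbered 398 and 82 after rescaling by the upper quartile, which was 10.5 FPKM in the Thy1.1-negative and 12.6 FPKM in the Thy1.1-positive library. Lower genes alone moved past 1.5 times under restrictions chosen after seeing the data, to 58 among protein-coding genes, 78 with at least 50 reads and 84 with an interval wholly past 1.5-fold. Of 310 alternative list values, 292 kept the call that a list stood apart, with its direction, or that it did not. Medians took the other sign in 11 cases, 5 of them in lists that stood apart. The upper quartile reversed the medians of the Treg signature (0.0615), naive (0.14), immediate early (0.0853) and ribosomal protein (0.0685) lists, while their percentiles stayed under 2.5. It moved the median of all genes by 0.23, and genes with low values by less. The other rescalings moved that median by -0.033 to -0.009. The quartile was taken over values above 0, which 28107 genes had in the Thy1.1-negative and 25709 in the Thy1.1-positive library. It therefore depends on how many near-silent genes were detected. Among lists that did not stand apart, the upper quartile turned the medians of the Th2 list (0.11) and the Foxp3 locus regulators (0.22). Without a filter the Th2 median was 0.0003, at a mean FPKM of at least 5 that of the Foxp3 locus regulators was 0.0143, and that of the sex-linked genes was -0.0087 when centred and -0.0086 without the 100 highest genes. The list of genes lower in Treg cells had a median of -0.0457 at a mean FPKM of at least 5. That filter left 9 members and dropped Dapl1 and Pde3b, whose differences of 0.68 and 1.14 were both positive. Without a filter the list had 12 members and a median of 0.18 at percentile 96.1, and the cause was not tested. B cell markers had a median of 0.0465 without a filter, which admits 7 more members with low values, and Th17 genes a median of 0.32 at percentile 97.2 with a pseudocount of 0.1; the cause was not tested. Scored by the share of members above the median gene, lists inside the range of random lists were the Treg signature (26.1%), genes lower in Treg cells (54.5%), naive (38.9%), Th1 (73.3%), Th17 (71.4%), Tfh (76.9%), interleukin-2 and STAT5 (25.0%) and B cell markers (66.7%). This score ignores the size of differences. Matched on length, the naive list (-0.12, percentile 2.67) and the respiration list (0.16, percentile 97.1) were inside it as well. Of 642 alternative values of named genes, 506 moved by at most 0.5 of the width of their counting interval and 136 by more, none of the genes past 2-fold with a change of sign. Calls of 2-fold ended for Il2ra, Gpr83, Swap70 and Ikzf4 by the upper quartile, and with a pseudocount of 5 for Evx1, Sdc4, Klrg1, Gpr83, Swap70, Cd40lg, Pde3b, Tbx21, Tmem176a, Sostdc1 and Pou2af1.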

Other observations

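The genes in the following paragraphs were chosen after their values were seen. They stand for no gene group. Vim, the intermediate filament vimentin, was higher in the Thy1.1-negative library, at 522 against 207 FPKM, with a ratio of 2.52 (2.43 to 2.61). Crip1 stood at 224 against 104 FPKM, Tagln2 at 148 against 69.9 FPKM and Myo1f, a class I myosin, at 42.8 against 9.62 FPKM. Ly6a, the surface antigen Sca-1, had a ratio of 2.75 (2.51 to 3.01) and Ly6c1 a ratio of 2.36 (2.03 to 2.76). Also higher there were Il9r, an interleukin-9 receptor chain, at 21.8 against 5.96 FPKM, Il1r2, the decoy receptor for interleukin-1, at 42.5 against 17.5 FPKM, and Cxcl10, a ligand of Cxcr3, at 93.9 against 32.6 FPKM. Ass1, an enzyme of arginine synthesis, stood at 344 against 149 FPKM. Zbtb32, a transcription factor, was 4.29-fold higher (3.34 to 5.57) and Cebpa, another, best known from myeloid cells, 3.51-fold higher (2.99 to 4.12). Il21, a Tfh cytokine with a mean FPKM under 1, had 54 reads in the Thy1.1-negative library and 1 in the Thy1.1-positive library, a ratio of 54.2 (9.32 to 2179).

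Gata1, a transcription factor best known from erythroid cells, was higher in the Thy1.1-positive library. It stood at 5.88 FPKM in the Thy1.1-negative library and 15.6 FPKM in the Thy1.1-positive library, a ratio of 0.377 (0.2998 to 0.472). Epas1, the hypoxia-inducible factor HIF-2 alpha, stood at 5.76 against 15.5 FPKM and Hoxb4 at 3.76 against 10.2 FPKM. Src, a tyrosine kinase, had a ratio of 0.490 (0.451 to 0.532) and Eno3, a muscle enolase, a ratio of 0.451 (0.400 to 0.508). Rn7sk, the small nuclear RNA 7SK, stood at 3.10 against 42.1 FPKM, in the same direction as Rpph1. Xist, the X-inactivation transcript, stood at 57.0 and 56.4 FPKM beside Y-linked Ddx3y at 60.5 and 60.1 FPKM, so transcripts typical of female and of male cells were present in both libraries.

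The tests of gene length and GC content were added after the data had been seen, but were written down before their own results were, and the tests on other cells, on DNA and on satellites were chosen only after the result was seen. The first pattern is the higher level of effector and cell cycle genes in the Thy1.1-negative library. A trend with gene length or GC content is argued against, since both lists lay at percentile 100 of random lists matched on expression and length and again at 100 when matched on expression and GC content, where the middle 95% of random medians ended at 0.145 or below. Lgals3 was higher in the same library but is in neither list, so a test of its source does not bear on those lists. Macrophages and monocytes in the sort, which bead enrichment for CD4 and the YFP gate select against, are argued against as the source of Lgals3. Lyz2, C1qa, C1qb, C1qc, Csf1r, Cd14 and Adgre1 together gained 0.326 FPKM, 2.21% of the Lgals3 gain of 14.8 FPKM. That sum leaves out Cst3 (63.5 against 50.1 FPKM) and Itgam (4.17 against 0.272 FPKM), the measured members of the myeloid list, both higher in the Thy1.1-negative library, and with them all 17 list members gained 17.5 FPKM, so other cells that express them stay open. Conventional T cells that lack the Treg signature, which the YFP gate selects against unless Cre had acted in them, cannot be told apart, as the cause of the lower Foxp3, from a difference between the sorted populations. Of the other 22 members, 15 had an interval wholly above that of Foxp3, 6 wholly below and 1 overlapping it, but these intervals cover counting error only and each population has 1 library.

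The second pattern is a higher level of satellite-like gene models in the Thy1.1-negative library, 13013 against 4075 reads over 9 models, each of them higher there. Such models match themselves, when shifted by the unit of the mouse major satellite, at 60% of bases or more, and most reads fell on Gm26870 (572 against 179 FPKM), without which the ratio was 3.38. Carried-over genomic DNA may contribute: 1620 olfactory and vomeronasal receptor genes with a mean FPKM of at most 0.2, which T cells barely express, had 2080 against 1409 reads, a ratio of 1.481 (1.38 to 1.59), and 4703 genes with a mean FPKM above 0 and at most 0.05 had 6940 against 3680 reads, a ratio of 1.89 (1.82 to 1.97). Both are under the satellite ratio of 3.204 (3.09 to 3.32), so DNA in equal measure over the genome does not account for it in full unless part of those reads have another origin. Transcription of satellites in cycling cells cannot be told apart from other differences, because each population has 1 library.

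The third pattern is the abundance of Ighm, the constant region of antibody heavy chain M, at 409 FPKM in the Thy1.1-negative and 258 FPKM in the Thy1.1-positive library. B cells in the sort, which the CD4 enrichment and YFP gate select against, are argued against as the source. Cd79a, Cd79b and Ms4a1, transcripts of the same cells, together reached 2.0% of the Ighm level in the Thy1.1-negative library and 2.37% in the Thy1.1-positive library, with Cd79b the most abundant at 6.45 and 3.97 FPKM. Plasma cells, low in those 3 transcripts, are not covered by that test; Jchain, one of their most abundant transcripts, stood at 0.440 and 0.779 FPKM. No biological explanation was tested.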
